A study of Homo sapiens with 6 samples.

How the data were processed

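Polyadenylated RNA of 6 libraries was sequenced on the DNBSEQ platform after TRIzol extraction, per the labels' protocols. The libraries form 2 groups of 3, by the hairpin in the sample titles (shNC or shSPP1#2). The sample labels name KYSE150 cells, whereas the series design text names THP1-derived macrophages kept in medium of those cells for 48 h. The cells were therefore examined by marker lists before any comparison, with no regrouping of samples. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

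The authors deposited a table of estimated counts per gene and a table of FPKM values per gene, each with 1 column per library and 17513 genes identified by Entrez number and symbol. HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM with build GRCh38.p13 are named per the submitters' processing notes, with no role or order. The deposited estimated counts were not scaled, and 78.9% to 80.4% of the values in a library were not whole (tolerance 0.005), as RSEM divides reads between genes and transcripts. Such division can move reads between near-identical or overlapping genes. Strand use, annotation release and filters are not given in the sources used here. The deposited FPKM values are fragments scaled by gene length and library total as the authors computed them, and how length and total were defined is not given in the sources used here. Stray lines of annotation text (20) were dropped from the FPKM values. Mitochondrially encoded genes were not analysed here.

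Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr (13555 kept), scaled by TMM and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3), shSPP1#2 minus shNC, with no block. Benjamini-Hochberg adjustment ran over all tested genes, and a gene was called at an adjusted p below 0.05. Standard errors and 95% intervals come from the same fit. The common dispersion gave a biological coefficient of variation of 4.54%. Total estimated counts ran from 18113591 to 20626346 per library, and the 10 most abundant genes took 8.81% to 9.44% of them. At this depth the median standard error of a log2 fold change was 0.065 among 10635 genes with a mean log2 CPM of at least 2. A floor of 3 counts over a group stands for a group at 0, and such a floor covers counting error only. The 95% intervals of the fit include the fitted spread between libraries.

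Gene lists (35) were written before the data were examined and tested with limma camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset correlation of 0.01, for the 33 lists with at least 5 tested members. Benjamini-Hochberg adjustment ran over these lists. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone. A list score per library is the mean over members of log2 CPM minus the gene's mean over the 6 libraries, and 2 groups of 3 were compared by a two-sided exact permutation test whose smallest p is 0.1. The rule for named genes, also fixed beforehand, took SPP1, up to 12 genes each with the largest rise and fall among called genes with a mean log2 CPM of at least 2 and groups that do not overlap (none qualified), the 10 genes of smallest p, and up to 4 genes of smallest adjusted p per list, with the 4 most abundant for the identity lists. CYREN was named after its position was seen, as the gene that overlaps TMEM140.

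The test was checked on counts simulated from the means, dispersions and library sizes of these libraries with 50 genes changed at each of several fold changes. The changed genes were drawn from the more abundant ones and planted in the same simulated counts. With no change simulated, 1 of 13436 genes was called. Coordinates, transcript length and GC content were taken from GENCODE v29 (GRCh38) by Entrez number, and 98.63% of genes had a length and GC value. Alternatives were RLE, upper-quartile and total-count scaling, no low-count filter or a CPM of at least 1 in 3 libraries, a replicate block, thinning to the smallest library, each library left out in turn, DESeq2 1.42.0 with and without its independent filter, edgeR with robust dispersion, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), an adjusted p below 0.01, and a correction for length and GC fitted with mgcv 1.9.3. Plots were drawn with matplotlib 3.10.9.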

Results

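RNA sequencing measured polyadenylated RNA in 6 libraries, in 2 groups of 3. The series description names the cells as macrophages derived from THP1, a human monocytic leukemia line. They were kept for 48 h in medium conditioned by KYSE150, a human esophageal squamous cell carcinoma line. The KYSE150 cells carried either shSPP1#2, a hairpin directed at SPP1, or shNC, the reference arm. SPP1 encodes osteopontin, a secreted glycoprotein that binds CD44 and several integrins. The question, as the series title frames it, is whether tumor SPP1 drives macrophages of the alternative, M2 type. Total estimated counts ran from 18113591 in shNC replicate 2 to 20626346 in shNC replicate 3, and 16069 to 16242 of the 17513 listed genes lay above 0. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 3.32 to 4.52, so no pair was treated as a single library deposited again; repeat preparations of one culture would also differ by more than counting noise.

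The libraries held macrophage RNA, whereas the sample labels name the KYSE150 line itself. Of 32 monocyte and macrophage genes, 29 reached 1 FPKM in each of the 6 libraries, and the list median lay between 52.3 and 53.6 FPKM. LAPTM5, a lysosomal membrane protein of blood cells, measured 725 to 823 FPKM, and the integrin ITGAX 281 to 314 FPKM. Of 34 squamous epithelial genes present among the deposited genes (41 listed), 7 or 8 reached 1 FPKM in a library. The median of those present lay between 0.090 and 0.185 FPKM. The most abundant of these were CSTA, a cysteine protease inhibitor, at 39.3 to 52.5 FPKM and PERP, a desmosome-associated membrane protein, at 23.5 to 25.7 FPKM. Medians of other marker lists, over members present, were 0.15 to 0.79 FPKM for fibroblasts, 0.75 to 1.18 FPKM for endothelium, 5.94 to 7.70 FPKM for T and NK cells, and 0.090 to 0.13 FPKM for B cells. Only 8 of 13 T and NK markers were present, and 5 or 6 of these reached 1 FPKM. No deposited gene was at 0 in all libraries, so undetected markers may be missing from these medians. GNLY, the granule protein granulysin, measured 214 to 274 FPKM. Groups are accordingly called shNC medium and shSPP1#2 medium here, with the direction taken from the hairpin named in each label.

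**Figure D1:**
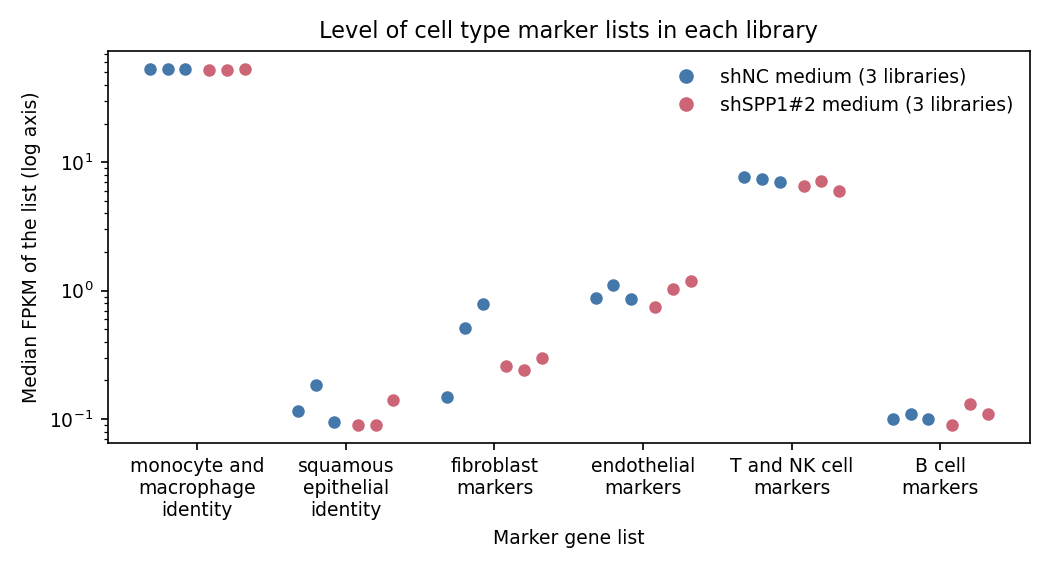
Median FPKM of 6 cell type marker lists, over members present among the deposited genes (log axis), 1 point per library, 3 libraries per group. The monocyte and macrophage list lies between 52.3 and 53.6 FPKM in all 6 libraries, and the squamous epithelial list between 0.090 and 0.185 FPKM.

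SPP1 itself was among the abundant transcripts of these cells and did not differ between the groups. Its level was 2075, 2011 and 1890.4 FPKM in shNC replicates 1, 2 and 3, and 2061, 2014 and 1932 FPKM in the shSPP1#2 replicates. The means were 1992 ± 93.6 FPKM (SD, n = 3) and 2002 ± 65.4 FPKM (SD, n = 3). The log2 fold change in the edgeR fit was 0.0025 with a standard error of 0.050 and a 95% interval from -0.10 to 0.11 (adjusted p = 0.998). SPP1 (Entrez 6696) lies on the plus strand of chromosome 4, 87975650 to 87983426, in GENCODE v29 on GRCh38. These values are of the receiving macrophages, not of the hairpin-bearing cells, so they do not check the knockdown.

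No single gene passed the threshold of adjusted p below 0.05 among the 13555 genes tested with edgeR, and the smallest adjusted p was 0.0655. The gene of smallest p, PSAT1, and another of the first 10, PHGDH, encode serine synthesis enzymes. PSAT1 was higher in shSPP1#2 medium by 0.36 on the log2 scale (95% interval 0.24 to 0.48, edgeR adjusted p = 0.0655), and PHGDH was higher by 0.28 (0.17 to 0.40). The mitochondrial folate enzyme ALDH1L2 was higher by 0.29, the lipoprotein receptor VLDLR by 0.23, the interferon-inducible SLFN5 by 0.29 and the chaperone CLGN by 0.62. S100A8, a calcium-binding protein of myeloid cells, had a log2 fold change of -0.62 (-0.87 to -0.37), the retinoid carrier CRABP2 of -0.29 and the ribosomal protein RPS29 of -0.24. None of these 9 genes had an edgeR adjusted p above 0.142. TMEM140 was at 0 counts in the 3 shNC libraries and at 12, 13 and 10 counts in the shSPP1#2 libraries (11.58, 12.56 and 9.71 before rounding). Against a floor of 3 counts over the shNC group it was 11.3-fold higher (edgeR adjusted p = 0.0655). That fold leaves out the error of the shSPP1#2 counts and of dividing reads between genes. TMEM140 lies on the plus strand of chromosome 7, 135148072 to 135166215, inside CYREN on the minus strand, 135092363 to 135170795 (GENCODE v29). Exons of CYREN cover 526 of its 2313 exonic bases (22.7%), and reads from that part are uncertain where strand was not used in counting.

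At an unadjusted p under 0.05 the edgeR test gave 928 genes, 468 higher and 460 lower in shSPP1#2 medium, where 677.75 would be reached with no change; the other splits of the 6 libraries into 3 and 3 gave 299 to 1457. DESeq2 called 13 genes, 8 higher and 5 lower, among them PSAT1, PHGDH, ALDH1L2, VLDLR, SLFN5, RPS29 and CRABP2. It adjusted over 4265 genes; adjusted over 17480, an alternative chosen after the data were seen, it called 12, with 9 of the 13 among them. The limma-voom fit called TMEM140 alone, and edgeR with robust dispersion called PSAT1, TMEM140 and CLGN. Without a low-count filter edgeR called 18 genes, among them the 10 of smallest p, and with the length and GC trend removed it called 3. Without shNC replicates 1, 2 or 3 edgeR called 3, 2 and 4 genes, and without shSPP1#2 replicates 1, 2 or 3 it called 1, 10 and 2. Groups did not overlap for 1508 genes (11.1%), where chance gives 10%. The differences were small: among 10635 genes with a mean log2 CPM of at least 2, 90% had an absolute log2 fold change under 0.14, and for 99.9% the 95% interval lay within 1 of 0. In counts simulated from these libraries (13434 genes in the step), edgeR recovered 46% of 50 genes changed 1.19-fold, 96% of 50 changed 1.41-fold and 100% of those changed 2-fold. The changed genes were drawn from the more abundant ones and all planted together, which eases the adjusted threshold. These shares therefore do not bound what was missed here. CLGN and S100A8, at log2 fold changes of 0.62 and -0.62, were not called (edgeR adjusted p = 0.128 and 0.142).

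**Figure D2:**
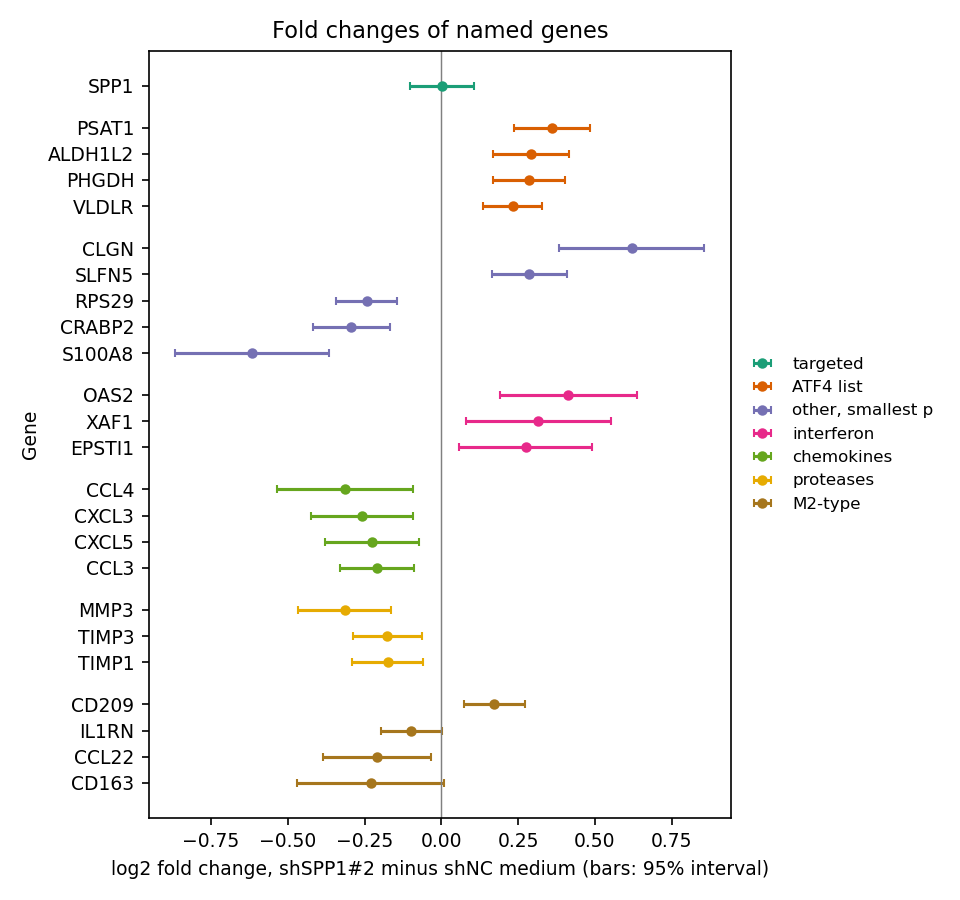
Log2 fold change of named genes, shSPP1#2 minus shNC medium, with 95% intervals from the edgeR fit (3 libraries per group), colored by gene group. PSAT1 stands at 0.36 and S100A8 at -0.62, while SPP1 lies at 0.0025.

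Of 35 gene lists, 33 had enough tested members, and 6 passed limma camera at a preset correlation of 0.01: 2 were higher and 4 lower in shSPP1#2 medium. Without shNC replicate 1, 12 lists passed. With an estimated correlation 0 passed, as with fry, which asks whether the members move one way. The estimate was 0.693 for ribosomal proteins but 0.0142 for type I interferon response, near the preset value. Estimating it also lowers the degrees of freedom, so a lost call alone does not show that members are correlated. The amino acid and integrated stress response list, made of targets and partners of the transcription factor ATF4, rose in shSPP1#2 medium. All 30 tested members had a positive log2 fold change, with a median of 0.17 (1.13-fold; limma camera adjusted p = 3.7e-16; adjusted p = 0.684 with an estimated correlation). Over all genes 0 members passed, and 19 passed adjusted over the list alone, all higher, PSAT1, PHGDH, ALDH1L2 and VLDLR among them (edgeR adjusted p = 0.00022 for PSAT1 and 0.00076 for each of the others). The mean score of the list was 0.17 higher in shSPP1#2 medium, and the 3 libraries of one group lay apart from the 3 of the other (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Scores were 0.157, 0.096 and 0.0040 in shSPP1#2 replicates 1, 2 and 3, and -0.048, -0.092 and -0.117 in the shNC replicates. That of shSPP1#2 replicate 3 lay closer to shNC replicate 1 than to the other shSPP1#2 libraries. Scores also lay apart for lists without a call: p53 targets, cell cycle, immune checkpoint ligands, and T and NK cell markers. Adjusted over the list alone, 10 members passed without shSPP1#2 replicate 1.

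Type I interferon response genes also rose as a list in shSPP1#2 medium, by a median of 0.084 over 38 tested members, of which 28 were higher and 10 lower (limma camera adjusted p = 4.3e-04, and 0.612 with an estimated correlation). OAS2, an activator of RNase L, was higher by 0.41 (95% interval 0.19 to 0.64), the apoptosis-linked XAF1 by 0.32 and EPSTI1 by 0.27. Over all genes 0 members passed, and adjusted over the list alone only OAS2 did (edgeR adjusted p = 0.0397). The list median was 0.047 without shNC replicate 2 and 0.13 without shNC replicate 3. The score of shNC replicate 2 was the lowest of the 6, at -0.064, close to the -0.059 of shNC replicate 1. In a principal component analysis shNC replicate 2 stood apart on the first component (22.5 against -10.5 to 1.63, 25.2% of the variance). On the second component (22.2% of the variance) shSPP1#2 replicate 2 stood apart, at 20.3 against -13.8 to 0.64. OAS2 did not pass without shNC replicate 1, shNC replicate 2, shSPP1#2 replicate 1 or shSPP1#2 replicate 2, where 0 members did.

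Chemokine genes fell as a list in shSPP1#2 medium, with a median log2 fold change of -0.15 over 17 tested members, 14 of them lower (limma camera adjusted p = 4.8e-04; adjusted p = 0.711 with an estimated correlation). The monocyte attractants CCL3 and CCL4 had log2 fold changes of -0.21 (-0.33 to -0.090) and -0.31 (-0.53 to -0.093), and the neutrophil attractants CXCL3 and CXCL5 of -0.26 and -0.23. These 4 passed adjusted over the list alone (edgeR adjusted p = 0.0296 for CCL3 and 0.0333 for the others), and 0 passed over all genes. CCL3 and CCL4 have near-identical copies in the genome, so their estimated counts are uncertain. With single libraries left out, CCL4 ran from -0.44 to -0.19, CXCL3 from -0.35 to -0.15 and CXCL5 from -0.30 to -0.10, and the list median from -0.25 (without shNC replicate 1) to -0.091 (without shNC replicate 3). The list call was lost without shSPP1#2 replicate 1 (median -0.13 over 19 members, limma camera adjusted p = 0.113) and without shNC replicate 2 (-0.10 over 19, adjusted p = 0.0548), where 0 members passed alone. Without shNC replicates 1 and 3 and shSPP1#2 replicates 2 and 3, 10, 2, 7 and 9 members passed alone. The score of shNC replicate 2, which stood apart on the first principal component, was the highest at 0.20. That of shNC replicate 1 was -0.081, below the 0.0025 of shSPP1#2 replicate 3. With each library's trend over transcript length and GC content removed, the median was -0.10 (limma camera adjusted p = 0.0139).

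Other inflammatory lists had no call. NF-kB targets had a median of -0.043 over 24 members (limma camera adjusted p = 0.0902), and inflammatory, M1-type macrophage genes one of -0.058 over 20 members (adjusted p = 0.235). Of these, CCL20 measured -0.13 (-0.25 to -0.018), the cytokine IL1A -0.13 and the signaling suppressor SOCS3 -0.16; 0 members of either list passed over all genes or adjusted over the list alone. With single libraries left out, CCL20 ran from -0.18 to -0.072, IL1A from -0.18 to -0.073 and SOCS3 from -0.25 to -0.10. The NF-kB list shares CXCL1, CXCL2, CXCL3, CXCL8 and CCL20 with the chemokine list, and the M1-type list shares CCL5 and CCL20. Without these, chosen after the data were seen, the medians were -0.021 over 19 and -0.040 over 18 members (limma camera adjusted p = 0.349 and 0.387). The M1-type list passed without shNC replicate 1 (limma camera adjusted p = 0.0040), where 3 members passed alone. The NF-kB list passed without shNC replicate 1 (adjusted p = 0.0027) and without shSPP1#2 replicate 2 (adjusted p = 0.0045), where 6 and 1 members passed alone, as 1 did without shSPP1#2 replicate 3.

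Matrix proteases and their inhibitors fell as a list, with a median of -0.054 over 27 members, 18 of them lower (limma camera adjusted p = 0.0028; adjusted p = 0.711 with an estimated correlation). The stromelysin MMP3 had a log2 fold change of -0.31 (-0.47 to -0.16), and the metalloprotease inhibitors TIMP3 and TIMP1 of -0.18 and -0.17. The lower members thus included a protease and inhibitors of that class. These 3 passed adjusted over the list alone (edgeR adjusted p = 0.0099 for MMP3 and 0.0442 for both inhibitors) and 0 over all genes. The list median ran from -0.11 without shSPP1#2 replicate 2 to -0.029 without shSPP1#2 replicate 1, and TIMP1 reached -0.11 without shNC replicate 2. The score of shNC replicate 2 was the highest, at 0.098, and with the length and GC trend removed the median was -0.039 (limma camera adjusted p = 0.0134). Alone, 7 and 0 members passed without shNC replicates 1 and 2, and 0, 5 and 1 without shSPP1#2 replicates 1, 2 and 3.

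Oxidative phosphorylation and cytosolic ribosomal protein genes fell as lists by small amounts in shSPP1#2 medium. The respiratory list had 29 of 32 members lower and a median of -0.065 (limma camera adjusted p = 4.4e-05; adjusted p = 0.711 with an estimated correlation), with COX6C at -0.20, COX7C at -0.15 and the complex I subunit NDUFA1 at -0.21. The ribosomal list had 29 of 30 members lower and a median of -0.073 (limma camera adjusted p = 6.2e-05; adjusted p = 0.832 with an estimated correlation), with RPS27 at -0.19 and RPS14 at -0.16. No member of either list passed over all genes or adjusted over the list alone. Without shNC replicate 3, 7 respiratory and 9 ribosomal members passed alone; without shSPP1#2 replicate 3, 1 respiratory member did, and without shSPP1#2 replicate 1, 5 ribosomal members. The ribosomal call was lost without shSPP1#2 replicate 3, where the median was -0.030 (limma camera adjusted p = 0.124). Without shNC replicate 2 the ribosomal median was -0.047, with RPS27 at -0.12 and RPS14 at -0.10. With each library's trend over transcript length and GC content removed, the medians were -0.043 for the respiratory and -0.038 for the ribosomal list (limma camera adjusted p = 0.0014 and 0.0149). Scores of shNC replicate 2 were again the highest, at 0.079 and 0.099, as was its score of the reference gene list, 0.056. That reference list had 19 of 24 members lower and a median of -0.030 (limma camera adjusted p = 0.127). Ribosomal scores overlapped between the groups: shNC replicate 3, at -0.039, lay below shSPP1#2 replicates 1 and 2 (two-sided exact permutation p = 0.3). Ribosomal protein genes have many processed pseudogenes, which makes their estimated counts uncertain.

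**Figure D3:**
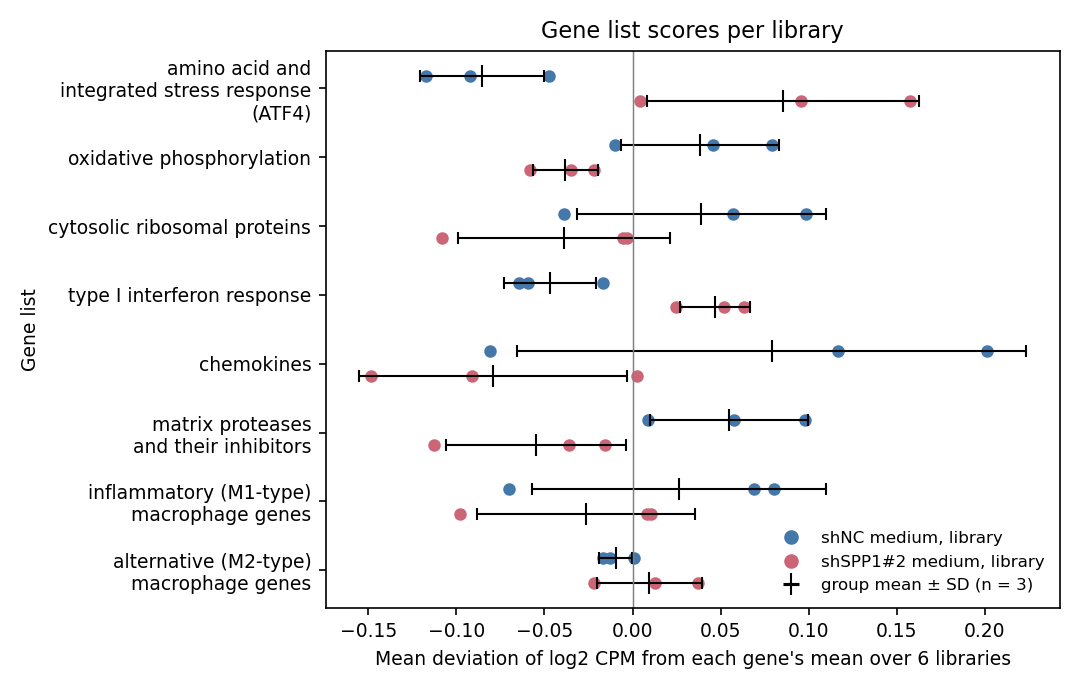
Scores of 8 gene lists per library: the mean deviation of log2 CPM from each gene's mean over the 6 libraries, with group means ± SD (n = 3). The shSPP1#2 scores of the ATF4 list all lie above the shNC scores, with group means of 0.086 and -0.086, while the M2-type list differs by 0.019.

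Alternative, M2-type macrophage genes showed no call in either direction. Of 31 listed genes 19 were tested, so the others add nothing to this result. The 19 tested members had a median of 0.017, with 10 higher and 9 lower (limma camera adjusted p = 0.920, and 0.929 with an estimated correlation). The lectin receptor CD209 was higher by 0.17 (0.074 to 0.27), the chemokine CCL22 measured -0.21 (-0.39 to -0.034), the IL-1 receptor antagonist IL1RN -0.098 and the scavenger receptor CD163 -0.23. Over all genes 0 members passed, and adjusted over the list alone CD209 did (edgeR adjusted p = 0.0314). With single libraries left out, CCL22 ran from -0.29 to -0.13 and IL1RN from -0.13 to -0.057. Without shNC replicate 1, 3 members passed alone, and 0 did without shNC replicate 2 or any 1 of the shSPP1#2 replicates. The 95% interval lay within 0.5 of 0 for 14 of the 19 members and within 1 for 16. Osteopontin and its receptors also had no call, with a median of -0.012 over 8 members (limma camera adjusted p = 0.920). ITGAV and ITGB1, integrin chains that bind osteopontin, measured 0.069 (-0.023 to 0.16) and -0.024 (-0.11 to 0.065); ITGB1 reached -0.014 without shNC replicate 2.

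Cell cycle genes had a median of -0.058 over 40 members and lipid handling and LXR target genes one of 0.036 over 26, both with a limma camera adjusted p of 0.0902. The cell cycle list passed without shNC replicate 1 (adjusted p = 0.0247), and the lipid list without shNC replicate 1 (adjusted p = 0.0130), without shSPP1#2 replicate 3 (adjusted p = 0.0055) and with the length and GC trend removed (adjusted p = 0.0281). The DNA helicase subunit MCM4 measured -0.14, the sterol exporter ABCG1 0.14 and the lysosomal lipase LIPA 0.13; without shSPP1#2 replicate 1, MCM4 was at -0.083 and LIPA at 0.073. Among lists of other cell types, collagen COL3A1 of the fibroblast list had a log2 fold change of -1.42 (-1.92 to -0.85 with single libraries left out). Its counts overlapped between the groups, 11, 23 and 44 in shNC medium against 16, 7 and 7. The receptor FLT1 of the endothelial list was higher by 0.19 (0.11 without shNC replicate 2). Both passed adjusted over the list alone and not over all genes, and neither list had a call (limma camera adjusted p = 0.363 and 0.387). No fibroblast member passed alone without shNC replicate 2 or 3 or shSPP1#2 replicate 2 or 3, and no endothelial member without shNC replicate 2 or shSPP1#2 replicate 1 or 3. Without shNC replicate 1, 2 members of each passed alone and the fibroblast list was called (adjusted p = 0.0129), as it was with no low-count filter (adjusted p = 0.0026); without shSPP1#2 replicate 2, 2 endothelial members passed. The macrophage and squamous identity lists had medians of 0.0099 and 0.018, while camera placed both lower (adjusted p = 0.505 and 0.560).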

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

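The correction for transcript length and GC and DESeq2 without its independent filter were chosen after the data were seen; the other settings were chosen before the data were examined. No scaling moved the median log2 fold change of all genes by as much as 0.1. Called genes numbered 0 with RLE, upper-quartile or total-count scaling, a CPM of at least 1 in 3 libraries, thinning, the 3 limma fits on log2 FPKM and an adjusted p below 0.01. Without a low-count filter edgeR called 18 genes (11 higher, 7 lower, 6 with an absolute log2 fold change of at least 1), with the length and GC correction 3 (2, 1 and 1), and with robust dispersion 3 (3 higher, 1 of at least 1). DESeq2 called 13 (8 higher, 5 lower, 0 of at least 1) adjusted over 4265 genes, 12 (8 higher, 4 lower, 2 of at least 1) without its independent filter, over 17480, and limma-voom 1 (1 higher, 1 of at least 1). Leaving out single libraries gave 1 to 10 genes, 0 to 4 higher, 0 to 7 lower and 1 to 5 of at least 1. With replicate number as a block edgeR called 59 genes (31 higher, 28 lower, 4 of at least 1) and 7 lists. Same-numbered libraries correlated across genes in their deviations from the group means by 0.073, 0.096 and 0.048. All lay under 0.1, the limit set, so the numbers were not taken as pairs. Still, 6 of 6 libraries correlated best with their own number. With the block 1461 genes had an edgeR unadjusted p under 0.05, against 928 without it. Low correlations do not show that pairing is absent, so it stays open. The SPP1 log2 fold change, 0.0025, was -0.00049 with upper-quartile scaling and -0.034 to 0.038 with single libraries left out, within its interval throughout. The number of called lists was 5 to 12 with single libraries left out (12 without shNC replicate 1), against 6, and stayed within 6 to 8 under the other scalings, filters and FPKM. It was 0 with an estimated correlation and 0 with fry. Adjusted p values were then 0.684 and 0.259 for the ATF4 list, 0.711 and 0.416 for oxidative phosphorylation, 0.832 and 0.701 for ribosomal proteins, 0.612 and 0.259 for interferon response, and 0.711 and 0.428 for both chemokines and matrix proteases. With single libraries left out the limma camera adjusted p ran from 3.79e-08 to 0.124 for ribosomal proteins and from 3.47e-05 to 0.113 for chemokines, and stayed below 0.05 for the other 4 lists. Squamous genes at 1 or more numbered at least 12 by CPM and 7 by FPKM. Genes given with a fold change in the comparisons kept their direction under each setting that tested them, SPP1 excepted. TMEM140 and COL3A1, at most 0.32 and 0.39 FPKM, were too low for the filters of 1 CPM or 1 FPKM in 3 libraries. With 9 of the 13 DESeq2 calls kept over more genes, the smaller number adjusted over was not the cause for those 9; other causes were not tested. Genes with few counts are limited by depth.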

Other observations

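Except for leaving out single libraries, which was planned before the data were examined, the tests here were chosen after the patterns they bear on had been seen.

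Aminoacyl-tRNA synthetase genes outside the ATF4 list split by compartment. Of 17 cytosolic synthetase genes 12 were higher in shSPP1#2 medium, with a median log2 fold change of 0.042, and 4 had an unadjusted p under 0.05, all higher. Of 17 mitochondrial synthetase genes 5 were higher, with a median of -0.023 and 0 at an unadjusted p under 0.05. Genes of a class are not independent replicates.

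The rise of ATF4 list genes in shSPP1#2 medium, a median of 0.17, was weighed against gene length and GC bias, single libraries and a wider ATF4 programme. With the length and GC trend fitted without the list removed, the median was 0.186 (bootstrap interval over members 0.14 to 0.20), which argues against that bias as the cause. Such an interval treats members as independent and leaves out the spread between libraries. Without shSPP1#2 replicate 1 the median was 0.137, with an interval of 0.080 to 0.18 that reaches under 0.086. A large part from that library thus stays open. The limma camera adjusted p at the preset correlation was at most 5.13e-10 with any 1 library left out. It cannot decide this, since a mixed split gave an unadjusted camera p of 2.65e-12 for the list. The hypothesis of a wider programme predicted cytosolic synthetase genes above mitochondrial ones, and the medians differed by 0.0654 (one-sided permutation p = 0.0177 over genes). These medians were not corrected for transcript length or GC content, so a length difference between the 2 classes stays open. A difference in the amino acid content of the media may underlie the pattern and was not tested; 10 splits of 6 libraries are too few for a share under 0.05, with 1 as extreme (real camera p 1.13e-17, smallest other 2.65e-12).

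The fall of ribosomal protein and oxidative phosphorylation genes, a median of -0.069 over 62 genes, goes along with transcript length: across genes the log2 fold change and length had a Spearman rho of 0.325, with a median of -0.084 for transcripts under 1000 bases. With the length and GC trend removed the median was -0.0425 (bootstrap interval over members -0.058 to -0.031). That interval lies around the -0.035 set as the limit, so bias and an effect on these genes cannot be told apart. Without shSPP1#2 replicate 3 the median was -0.0396 (-0.057 to -0.025), which also leaves a single library open. Other splits gave length correlations of up to 0.447 in size, and 3 of the 10 splits gave as small a camera p for ribosomal proteins (real 5.61e-06, smallest other 2.17e-11), too few splits for a share under 0.05. A length-dependent difference between libraries, such as in RNA integrity or library preparation, may contribute.

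The sample labels name carcinoma cells, but the highest squamous list median in a library, 0.185 FPKM, lay below the lowest macrophage list median, 52.3 FPKM, which argues against KYSE150 RNA as the main content. No biological explanation of this label conflict was tested.

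With 0 genes called in the real split, all 10 splits of the 6 libraries necessarily called as many, so that count says nothing about chance (highest other 4). For lists, 4 of 10 splits called as many (real 6, highest other 12), and 10 splits are too few for a share under 0.05. By list, the unadjusted limma camera p of the real split and the smallest of the others were 7.35e-05 and 4.21e-06 for chemokines, 5.14e-04 and 4.65e-04 for matrix proteases, 5.22e-05 and 4.85e-04 for interferon response, and 2.70e-06 and 4.42e-06 for oxidative phosphorylation. For chemokines and proteases a mixed grouping thus gave a smaller p than the real one.

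Some of the largest fold changes lay in near-identical gene pairs, named after their values were seen. HBA2 was at 20, 6 and 23 counts in shNC medium and 0 in each shSPP1#2 library, while HBA1 and HBA2 together summed to 27.3 ± 7.02 and 20.7 ± 6.43 counts (SD, n = 3). SMIM11A averaged 98.0 ± 21.8 and 31.0 ± 43.7 counts, and the sum with SMIM11B 200 ± 30.2 and 186 ± 15.5. TMEM140 and HBA2 were the 2 genes at 0 throughout one group and at 5 or more counts in each library of the other; other splits gave up to 3 such genes. Among 25 genes with an unadjusted p under 0.01 and an absolute log2 fold change of at least 0.75, 78.7% of values were not whole, against 68% to 90% in draws of genes of the same mean count (permutation p = 0.585).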
